A study of Columba livia with 12 samples.

How the data were processed

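Livers of white king pigeons were sampled at 1 day, 14 days, 28 days and 2 years of age, with 16 birds per age. The 48 squabs were of mixed sex, and the 16 parents, aged 2 years, were 8 males and 8 females. Per the labels' protocols, RNA was extracted with TRIzol and checked on a Bioanalyzer 2100, and 3 pigeons per age were sequenced, each as its own library. RNA of 10 to 45 nt was selected on a gel, and 50 bp single-end reads were made on a HiSeq 2500. Bowtie is named in the submitters' processing notes. Its version, the genome build, the program that assigned reads to miRNAs and the handling of reads that match several miRNAs are not given in the sources used here. The deposited table holds raw read counts per mature miRNA, per the file headers. Each column matches the title of 1 library. The descriptions of 2 libraries titled 1d, replicates 2 and 3, name pigeons of 2 and 3 days, while their stage label is 1d, and the titles were used for grouping.

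The table has 1039 mature names. Of these 324 carry a pigeon name and hold 99.8% of the counts, 502 carry the prefix of conserved names (0.117%) and 213 the prefix of predicted ones (0.0350%). Every entry names a miRNA. Total counts were 3100273 to 9393075 per library, a ratio of 3.03. A count of 0 allows up to 3 counts, which is 0.326 to 1.90 CPM on the TMM scale depending on the library. Such floors cover counting error only, since the reads carry no molecular identifiers. Libraries of one age differed far beyond sampling noise, so none was taken for a repeat of another.

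Counts were analysed with edgeR 4.0.16 in R 4.3.3. miRNAs were kept by filterByExpr with the ages as groups (345 kept), library sizes were scaled by TMM (factors 0.512 to 1.96), and a quasi-likelihood model with one mean per age and robust dispersion was fitted over all 12 libraries. The common biological coefficient of variation was 0.807. Each of 6 pairs of ages and the 4 ages together were tested, with the Benjamini-Hochberg adjusted p under 0.05 as the threshold. Adjusted p values of single miRNAs in the text come from this edgeR test unless another tool is named. Levels are CPM, the deposited counts relative to TMM-scaled library sizes, and fold changes and log2 fold changes are the fitted ones. Shares of counts are raw percentages of a library's total. The TMM factors followed age, at 1.61 to 1.96 at 1d, 1.30 to 1.56 at 14d, 0.512 to 0.953 at 28d and 0.568 to 0.730 at 2y. On the CPM scale a change from 1d or 14d to 28d or 2y therefore lies above the change in share of counts.

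Lists of miRNA families were fixed before the data were examined, as were the tests, the alternatives and the rule for naming miRNAs. There were 18 lists: hepatocyte-enriched, let-7, miR-17-92, embryonic cluster, miR-30, miR-29, miR-34, lipid metabolism, erythroid, leukocyte, endothelial, mesenchymal, biliary and other epithelial, muscle, neural, pancreas, the group of miR-10, miR-99, miR-100 and miR-125, and Z-linked male-biased. Members of the families miR-122, miR-192, miR-98, miR-427, miR-430, miR-378, miR-144, miR-451, miR-486, miR-223, miR-150, miR-203, miR-206, miR-208 and miR-219 were not analysed here. Lists with at least 3 tested members were tested with camera on voom values (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over lists within a comparison. Shares of lists and measures of library composition were compared over the ages by an exact permutation of the one-way F statistic over all 15400 partitions of the libraries, two-sided by construction, with a smallest possible p of 6.5e-05. No pair of ages was tested in this way, since 3 libraries against 3 cannot reach the threshold.

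For 14d against 1d, 28d against 14d, 2y against 28d and 2y against 1d, the miRNAs named are the 6 largest rises and 6 largest falls among those that passed, had a mean of at least 100 CPM at either age and no overlap between the libraries. The rule also takes up to 4 members of each list by smallest adjusted p with at least 100 CPM, the 5 most abundant miRNAs, and miR-2954, of which the text prints a part. The other 2 comparisons name 3 rises and 3 falls. miR-92-3p between 1d and 14d, miR-217-5p, miR-124-3p, miR-181a-3p and miR-456-5p between 28d and 2y, and miRNAs first named in the closing section, were chosen after their values were seen. Counts of miR-103-3p and miR-107-3p, of miR-30a-3p and miR-30e-3p, and of let-7a-3p and let-7e-3p lie within 10% of each other in every library, and these pairs are uncertain because their reads may be shared.

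The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 miRNAs changed by known folds. In the order 14d against 1d, 28d against 14d, 2y against 28d, 2y against 1d, 28d against 1d and 2y against 14d, the share of tested 2-fold changes called was 16.4, 5.08, 12.7, 7.41, 11.9 and 8.20%. For 4-fold changes it was 47.4, 49.1, 45.8, 51.7, 46.3 and 36.8%, and for 8-fold changes 63.8, 60.7, 60.3, 71.7, 59.0 and 59.7%. The number of tested miRNAs in these runs was 355, 354, 375, 334, 356 and 369. A list changed 4-fold was called in 6 of 6 runs and unchanged lists in 0. Apart from the planted changes, every age had the same mean and the same dispersion per miRNA. The shares called therefore do not measure the power of a comparison with a wider spread or fewer changes. The miRNAs of these runs were drawn independently of each other. The runs therefore do not show how often the list test errs when members are correlated.

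Alternatives were other scalings (relative log expression, upper quartile, total count only), the most abundant miRNA left out, no filter and a stricter one (10 CPM in 3 libraries), DESeq2 1.42.0, limma voom, a fold threshold, the replicate number as a block, only the 6 libraries compared, and each library left out in turn. Leaving out miRNAs with 0 counts in 1 or 2 libraries of an age and at least 100 in another of that age was added after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.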

Results

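Small RNA was sequenced from the livers of white king pigeons (Columba livia), a breed of the domestic pigeon. Birds were taken at 4 ages: 1 day (1d), 14 days (14d), 28 days (28d) and 2 years (2y). Each age had 3 libraries, and each library came from 1 pigeon. The youngest 3 groups were squabs, the nestlings of pigeons, and the oldest were adult parent birds. The series asks how the miRNA profile of the liver differs over development. The values are raw read counts for 1039 mature miRNA names, of which 102 had no count in any library. Total counts lay between 3100273 and 9393075 per library, and 345 miRNAs had enough counts to be tested. The prefix cli- of the file's names is left out below, and every mean is given ± SD over n = 3 pigeons.

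A few miRNAs made up most of the counts, and their order differed between ages. miR-148a-3p, an abundant hepatocyte miRNA, held 17.7 ± 2.34, 5.97 ± 0.393, 20.8 ± 4.25 and 17.3 ± 1.30% of the counts at 1d, 14d, 28d and 2y. In the same order miR-26-5p held 12.4 ± 2.16, 16.8 ± 4.19, 20.4 ± 5.68 and 21.4 ± 3.48%. miR-22-3p held 4.60 ± 0.703, 18.8 ± 2.84, 13.0 ± 4.83 and 16.7 ± 3.21%, and miR-143-3p, known from smooth muscle and other mesenchymal cells, held 6.83 ± 0.736, 2.73 ± 0.610, 9.41 ± 3.33 and 13.2 ± 3.42%. The 10 most abundant miRNAs of a library together held 70.0 ± 1.35% at 1d, 71.7 ± 0.744% at 14d, 82.9 ± 6.32% at 28d and 84.5 ± 1.95% at 2y (exact permutation test over 15400 partitions of the libraries, adjusted p = 0.0118). The number of miRNA names with a count was 433 ± 16.4, 503 ± 1.00, 349 ± 63.2 and 359 ± 18.8 (adjusted p = 0.0118). Total counts did not pass this test (adjusted p = 0.118). The age groups differed in 156 of 345 miRNAs in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The first component of log2 CPM held 27.9% of the variance and the second 21.0%.

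**Figure D1:**
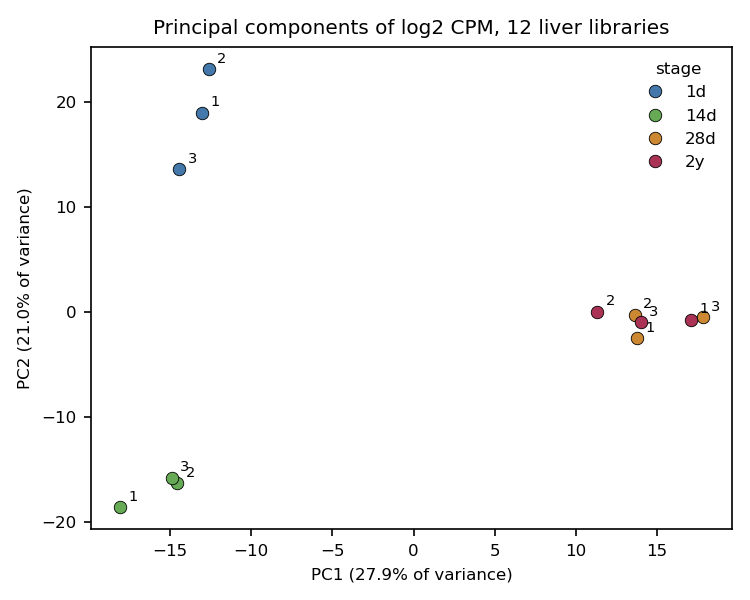
Principal components of log2 CPM, with component 1 (27.9% of variance) on the x axis and component 2 (21.0%) on the y axis; each point is 1 library, numbered by replicate and coloured by stage. The 1d libraries lie at 13.6 to 23.2 and the 14d libraries at -18.6 to -15.8 on component 2, while the 28d and 2y libraries share one area at 11.3 to 17.8 on component 1.

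The share of all counts held by each miRNA list fixed before the data were examined was compared over the 4 ages with the same exact permutation test, adjusted over 17 lists. Of these, 11 differed. The hepatocyte-enriched list, of which miR-148a-3p made up 99.4%, held 17.8 ± 2.34, 6.04 ± 0.380, 20.9 ± 4.23 and 17.4 ± 1.36% at 1d, 14d, 28d and 2y (adjusted p = 0.0142). The mesenchymal list (miR-143, miR-145, miR-199 and miR-214) held 8.89 ± 0.954, 4.62 ± 0.847, 11.3 ± 3.19 and 15.5 ± 3.48% (adjusted p = 0.0135), and miR-143-3p made up 80.7% of it. The miR-29 family, whose known targets include collagen mRNAs, held 0.0286 ± 0.00408, 0.0441 ± 0.00971, 0.0897 ± 0.0670 and 0.148 ± 0.0236% (adjusted p = 0.0483), with 0.0511% at 28d without 28d replicate 1. Of this family's counts miR-29a-3p made up 84.1%. The miR-17-92 family, known for its part in cell proliferation, held 4.66 ± 0.283, 6.36 ± 3.49, 0.721 ± 0.175 and 0.993 ± 0.0215% (adjusted p = 0.0135), and miR-92-3p made up 80.3% of it. The let-7 family, which is linked to cell differentiation, held 2.53 ± 0.252, 3.34 ± 0.545, 1.12 ± 0.479 and 1.78 ± 0.511% (adjusted p = 0.00442). The lipid metabolism list (miR-33, miR-27, miR-103, miR-107 and miR-34) held 1.22 ± 0.0812, 1.20 ± 0.0570, 0.645 ± 0.0925 and 0.650 ± 0.0264% (adjusted p = 0.0142). With TMM 3 of its 10 tested members rose and 0 fell between 1d and 28d, and 1 rose and 0 fell between 1d and 2y. With the total count alone 0 rose and 4 fell in both comparisons. The counts of miR-103-3p and miR-107-3p in this share may come from the same reads.

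The biliary and other epithelial list (miR-200, miR-141, miR-429, miR-205, miR-183, miR-96 and miR-182) held 0.127 ± 0.00978, 0.260 ± 0.150, 0.0603 ± 0.0337 and 0.0436 ± 0.00147% (adjusted p = 0.00442). The muscle list held 0.272 ± 0.149, 0.366 ± 0.151, 0.105 ± 0.0724 and 0.0380 ± 0.00595% (adjusted p = 0.0483), the neural list 0.0464 ± 0.0150, 0.0923 ± 0.0101, 0.0184 ± 0.0197 and 0.00952 ± 0.00171% (adjusted p = 0.0110) and the pancreas list 0.0104 ± 0.00459, 0.0651 ± 0.0157, 0.0193 ± 0.0162 and 0.0225 ± 0.00854% (adjusted p = 0.0150). Single miRNAs made up most of each, miR-133a-3p 75.2% of the muscle, miR-9-5p 60.4% of the neural and miR-375-3p 93.7% of the pancreas list. miR-2954, encoded on the Z chromosome and higher in male birds, held 0.443 ± 0.0572, 1.90 ± 0.611, 0.418 ± 0.436 and 0.171 ± 0.0144% (adjusted p = 0.0163), and the sex of the sequenced birds is not given. The remaining lists did not pass. The leukocyte list held 4.01 ± 1.19, 1.88 ± 0.362, 5.32 ± 3.43 and 2.89 ± 0.275% (adjusted p = 0.158) and the endothelial list, made up of miR-126, 4.08 ± 1.06, 2.44 ± 0.293, 2.80 ± 1.14 and 2.21 ± 0.0824% (adjusted p = 0.0679). The miR-30 family held 19.6 ± 4.61, 14.7 ± 3.43, 12.2 ± 6.63 and 10.9 ± 1.10% (adjusted p = 0.171), the group of miR-10, miR-99, miR-100 and miR-125 2.21 ± 0.441, 4.95 ± 0.760, 3.07 ± 2.46 and 2.23 ± 0.433% (adjusted p = 0.134) and the miR-34 family 0.00442 ± 0.00189, 0.00673 ± 0.00233, 0.00620 ± 0.00440 and 0.0141 ± 0.0134% (adjusted p = 0.422). The embryonic cluster reached at most 7.05e-05% in any library (adjusted p = 0.193). Without 28d replicate 1 the shares at 28d were 0.00699% for the neural list, 0.167% for miR-2954, 3.48% for the leukocyte list and 1.66% for the group of miR-10, miR-99, miR-100 and miR-125. Without 28d replicate 3 they were 0.0637% for the muscle list and 0.00997% for the pancreas list. The epithelial share at 14d was 0.173% without 14d replicate 1, and the miR-34 share at 2y was 0.00665% without 2y replicate 3. The erythroid list and miR-122 were not analysed here.

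**Figure D2:**
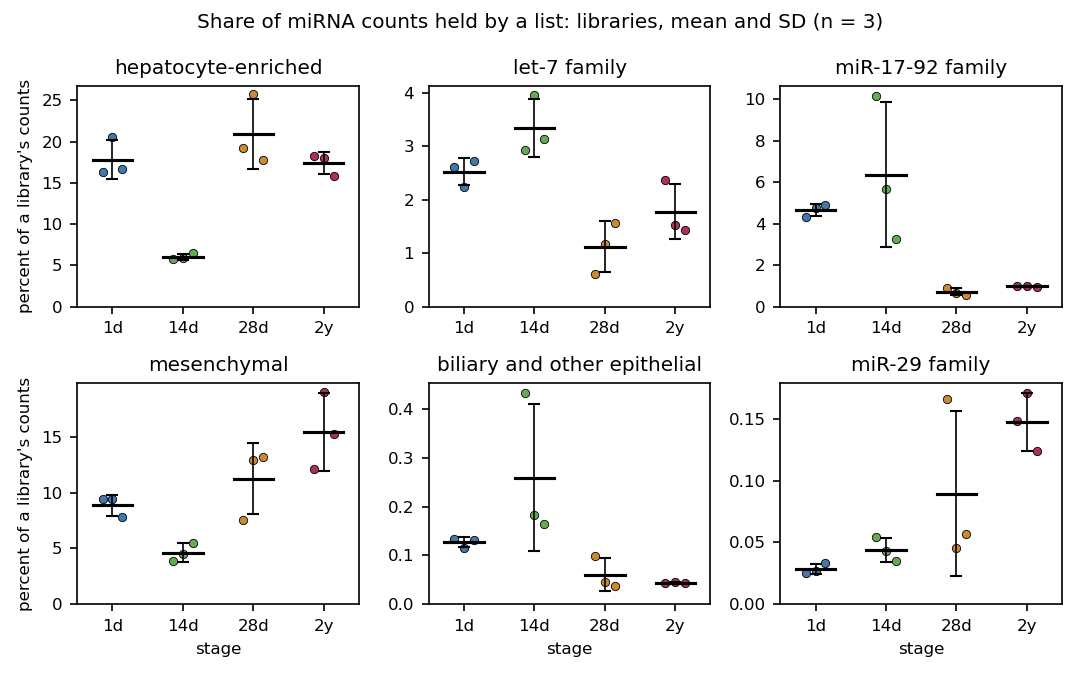
Share of a library's miRNA counts (y axis, percent) held by 6 lists at each stage (x axis); points are libraries, with the mean and SD over 3 pigeons. The hepatocyte-enriched share was lowest at 14d (6.04%), and the miR-17-92 share was 4.66% and 6.36% at 1d and 14d but 0.721% and 0.993% at 28d and 2y.

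Between 1d and 14d, 107 of 345 miRNAs changed, 58 of them higher and 49 lower at 14d. miR-22-3p rose 5.03-fold (135350.0 ± 18149 against 26886 ± 5117 CPM, log2 fold change 2.33 ± 0.47 SE, adjusted p = 0.00545). miR-181a-5p rose 5.84-fold (37584 ± 6391 against 6439.7 ± 1362 CPM, adjusted p = 0.00316) and miR-2954-3p 5.41-fold (13611 ± 4729.9 against 2516 ± 204 CPM, adjusted p = 0.00290). The other rises of the naming rule were miR-214-3p (9.78-fold, or 6.18-fold without 14d replicate 1), miR-375-3p, a pancreatic islet miRNA (7.94-fold), miR-1388-3p (7.55-fold) and the minor arm miR-30c-3p (5.20-fold), with adjusted p from 0.000481 to 0.00643. Among the falls, miR-30e-5p dropped 3.91-fold (15866 ± 4547 against 62054 ± 16044 CPM, adjusted p = 0.00154).

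Of 19 tested members of the miR-17-92 family 0 rose at 14d, 10 fell and 9 did not pass (adjusted over the list alone, 1 up and 10 down, and with the total count alone 0 up and 9 down). The family's share of counts was 4.66 ± 0.283% at 1d and 6.36 ± 3.49% at 14d. Its most abundant member, miR-92-3p, was at 43944 ± 27491 against 19639 ± 3648 CPM and did not pass (adjusted p = 0.0829), with 74911 CPM in 14d replicate 1 and 34504 and 22416 CPM in replicates 2 and 3. Members that fell include miR-18b-5p (14.4-fold lower, or 22.1-fold without 14d replicate 1), miR-106-3p (6.82-fold), miR-363-3p (5.73-fold) and miR-106-5p (4.69-fold), with adjusted p from 0.000254 to 0.000676. In camera the list had an adjusted p = 3.13e-06 with the preset correlation and an adjusted p = 0.564 with an estimated correlation. miR-142, made in blood-forming cells, was lower at 14d on both arms, miR-142-5p 3.14-fold (3335 ± 419 against 10459 ± 5075 CPM) and miR-142-3p 4.38-fold, while miR-146b-3p of the same leukocyte list was 3.77-fold higher. Over that list of 11, 2 rose and 2 fell, the same counts adjusted over the list alone and 2 up and 2 down with the total count alone (camera adjusted p = 0.854). In the group of miR-10, miR-99, miR-100 and miR-125 3 of 9 rose and 1 fell (adjusted over the list alone, 4 up and 1 down, and with the total count alone 2 up and 1 down), with miR-125-5p 5.04-fold higher (16099 ± 5892 against 3194 ± 597 CPM) and the minor arm miR-100-3p 12.7-fold lower (19.4-fold without 14d replicate 1).

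The mesenchymal list had 4 of 10 members higher and 0 lower at 14d (adjusted over the list alone, 5 up and 0 down, and with the total count alone 1 up and 1 down; camera adjusted p = 0.468), and miR-143-3p was at 19882 ± 5483 against 39764 ± 4793 CPM and did not pass (adjusted p = 0.119). In the let-7 family 4 of 14 rose and 3 fell (adjusted over the list alone, 4 up and 3 down, and with the total count alone 2 up and 3 down), with let-7d-3p 5.02-fold higher (3.13-fold without 14d replicate 1). The epithelial list had 3 of 10 members higher and 0 lower (adjusted over the list alone, 3 up and 0 down, and with the total count alone 2 up and 0 down), with miR-200b-3p 2.77-fold higher. In the hepatocyte-enriched list 2 of 6 fell and 0 rose (adjusted over the list alone, 0 up and 2 down, and with the total count alone 0 up and 1 down), and miR-148a-3p was 2.39-fold lower (43381 ± 6003 against 103804 ± 21788 CPM, adjusted p = 0.0143). That last call ended without 1d replicate 2 or 14d replicate 2 (adjusted p 0.0507 to 0.0516). The largest falls outside the lists, among called miRNAs of at least 100 CPM at either age, were those of miR-2188-3p and miR-3156-5p. miR-2188-3p was 18.3-fold lower (31.5-fold without 14d replicate 1). miR-3156-5p, a conserved name, was at 746 ± 272 CPM at 1d and 0 in every 14d library. By a floor of 3 counts per library it was at least 1752-fold lower, and its call ended without any 1 of the 6 libraries (adjusted p 0.0671 to 0.0860). miR-30d-3p, the minor arm of miR-30d, was 15.2-fold lower (adjusted p = 7.24e-05).

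With scaling to the total count alone 78 miRNAs passed between 1d and 14d, 30 higher and 48 lower, and the median log2 fold change of all tested miRNAs shifted by -0.31. With TMM, leaving out any single 1d or 14d library left between 50 and 68 calls, 24 to 37 higher and 22 to 40 lower. The balance turned without 28d replicate 1 (51 higher and 67 lower), 2y replicate 1 (40 higher and 45 lower) or 2y replicate 3 (39 higher and 41 lower), and also without 1d replicate 1 or 2 or 14d replicate 1. More were lower also with relative log expression (46 higher and 60 lower), DESeq2 (54 and 67) or the stricter filter (37 and 56). The same held with no filter (15 and 33), the replicate block (33 and 37) or only the 6 libraries compared (58 and 71). Without miRNAs at 0 in part of an age's libraries the split was 44 and 62. More were higher with upper-quartile factors (59 and 50), limma voom (85 and 56) or the most abundant miRNA left out (52 and 51).

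**Figure D3:**
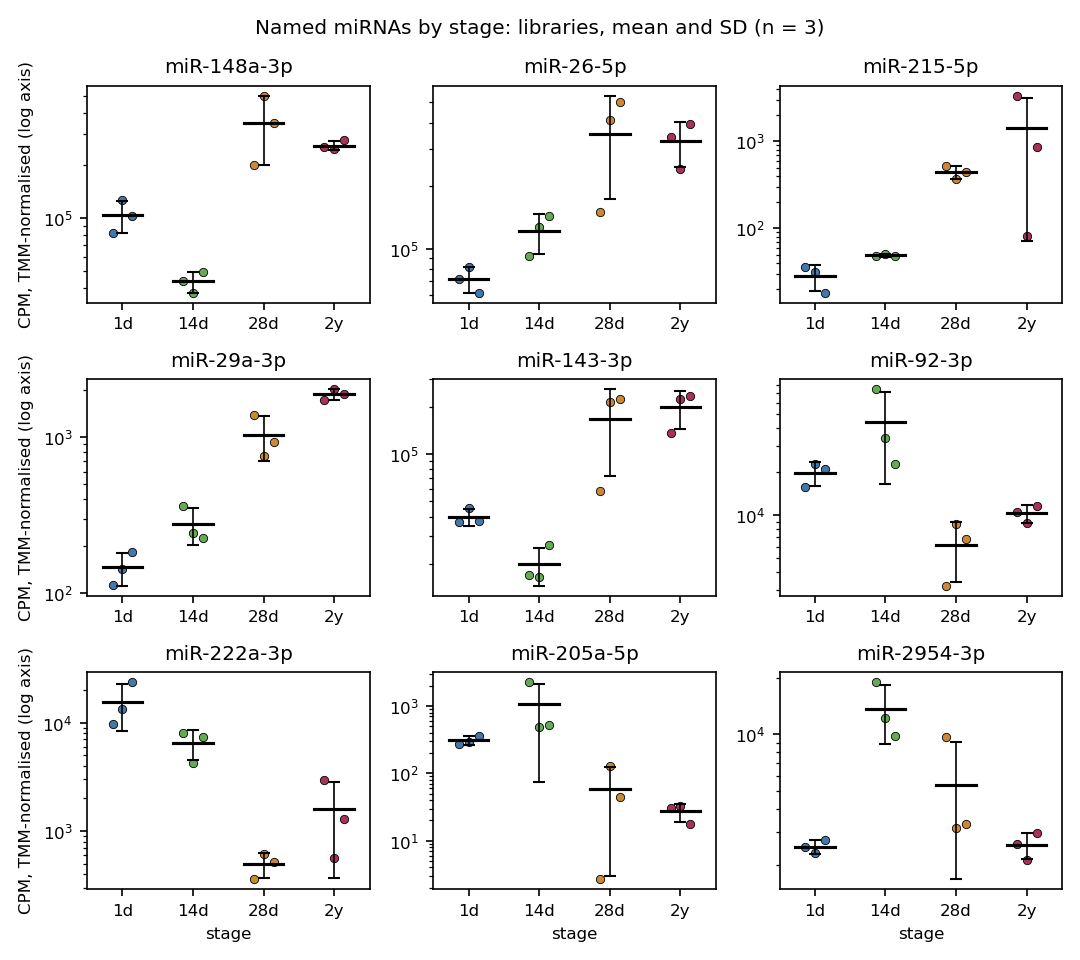
CPM with TMM normalisation (log y axis) of 9 named miRNAs at each stage (x axis); points are libraries, with the mean and SD over 3 pigeons. miR-29a-3p had mean values of 146, 276, 1027 and 1880.1 CPM at 1d, 14d, 28d and 2y, and miR-215-5p ranged from 82.1 to 3327 CPM among the 2y libraries; with scaling to the total count alone, miR-148a-3p had a log2 fold change of -0.04 from 1d to 2y.

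Between 14d and 28d, 97 miRNAs changed, 54 higher and 43 lower at 28d. miR-148a-3p rose 8.04-fold (348764 ± 148791 against 43381 ± 6003 CPM, log2 fold change 3.01 ± 0.33 SE, adjusted p = 0.000345). Its share of counts was 5.97% at 14d and 20.8% at 28d. miR-143-3p rose 8.38-fold (166703 ± 93913 against 19882 ± 5483 CPM, adjusted p = 0.00124) and its neighbour in the genome of other vertebrates, miR-145-3p, 15.3-fold (adjusted p = 0.000345, and 8.38-fold without 28d replicate 1). miR-33-5p, which lies in an intron of the gene for a sterol regulatory factor, rose 9.50-fold (180.5 ± 94.8 against 19.0 ± 9.14 CPM, adjusted p = 0.000771, and 6.22-fold without 28d replicate 1), and miR-190-5p rose 10.2-fold (adjusted p = 0.000345). miR-222a-3p fell 13.1-fold (501 ± 131 against 6541 ± 2053 CPM, adjusted p = 0.00153), miR-92-3p 7.08-fold (6207 ± 2767 against 43944 ± 27491 CPM, adjusted p = 0.00165), miR-31-5p 7.97-fold (4.77-fold without 14d replicate 1) and let-7d-3p 6.82-fold.

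In the leukocyte list 5 of 11 members rose and 0 fell (adjusted over the list alone, 5 up and 0 down, and with the total count alone 4 up and 2 down; camera adjusted p = 0.174). miR-146b-5p, a miRNA induced in immune responses, was 10.5-fold higher (13246 ± 8838 against 1265 ± 347 CPM), miR-142-3p 7.60-fold, miR-142-5p 5.56-fold and miR-146c-5p 5.04-fold, with adjusted p from 0.000483 to 0.00165. The 28d libraries were not alike in this list, whose share was 8.99% in replicate 1 and 2.20% and 4.75% in replicates 2 and 3. The epithelial list had 5 of 10 members lower and 0 higher (adjusted over the list alone, 0 up and 5 down, and with the total count alone 0 up and 8 down; camera adjusted p = 0.174). miR-205a-5p was 18.3-fold lower (59.3 ± 65.0 against 1085 ± 1010.3 CPM), a call that ended without 14d replicate 1 or 28d replicate 3 (adjusted p 0.0731 to 0.0752). The fall was 9.42-fold without 14d replicate 1, 11.9-fold without 28d replicate 1 and 44.9-fold without 28d replicate 2. In the miR-30 family 3 of 8 rose and 1 fell (adjusted over the list alone, 3 up and 1 down, and with the total count alone 1 up and 2 down), with miR-30e-5p 4.71-fold higher (74762 ± 23527 against 15866 ± 4547 CPM, adjusted p = 0.000655). Of the 4 tested miR-29 members 2 rose and 0 fell (adjusted over the list alone, 2 up and 0 down, and with the total count alone 1 up and 0 down), with miR-29b-3p 5.58-fold higher (adjusted p = 0.00109, and 3.54-fold without 28d replicate 1).

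The miR-17-92 family had 3 of 19 members higher, 4 lower and 12 that did not pass, the same counts adjusted over the list alone and 0 up and 8 down with the total count alone. miR-20a-5p was 2.54-fold and miR-19b-3p 3.32-fold higher. In the let-7 family 2 of 14 rose and 3 fell (adjusted over the list alone, 2 up and 4 down, and with the total count alone 0 up and 8 down), with let-7d-5p 5.35-fold and let-7f-5p 5.83-fold lower, the latter 3.75-fold without 14d replicate 1. The mesenchymal list had 4 of 10 members higher and 1 lower, the latter miR-214-3p (3.63-fold; adjusted over the list alone, 4 up and 2 down, and with the total count alone 2 up and 2 down). In the hepatocyte-enriched list 3 of 6 rose and 1 fell, the same counts adjusted over the list alone and 1 up and 2 down with the total count alone. That list holds both arms of miR-148a, and the minor arm miR-148a-5p fell 2.76-fold (127 ± 30.7 against 352 ± 73.9 CPM, adjusted p = 0.00387). miR-215-5p, which shares its seed with miR-192, was 9.12-fold higher (448 ± 76.0 against 49.2 ± 1.88 CPM), a call that ended without any 1 of the 6 libraries (adjusted p 0.0563 to 0.119). Both arms of miR-2954 were lower at 28d, the 3p arm 2.53-fold (5369 ± 3682 against 13611 ± 4729.9 CPM, or 4.51-fold without 28d replicate 1) and the 5p arm 5.91-fold (15.3-fold without 28d replicate 1). The call of the 3p arm ended without any 1 of 11 of the 12 libraries, all but 28d replicate 1 (adjusted p 0.0525 to 0.165), and the call of the 5p arm without 14d replicate 1 or 2 or 28d replicate 2 or 3 (adjusted p 0.0611 to 0.104).

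With scaling to the total count alone 116 miRNAs passed between 14d and 28d, 18 higher and 98 lower, with a median shift of -1.01 in log2; miR-20a-5p, miR-19b-3p and miR-215-5p then no longer passed (adjusted p 0.453, 0.197 and 0.110). With TMM, leaving out any single 14d or 28d library but 28d replicate 1 left 36 to 48 higher and 23 to 26 lower (in all 61 without 14d replicate 1 and 62 without 14d replicate 2). Without 28d replicate 1 there were 45 higher and 46 lower, and without 2y replicate 2 or 3 there were 27 lower. More were lower with upper-quartile factors (40 higher and 61 lower), DESeq2 (61 and 66) or limma voom (56 and 67). With relative log expression the split was 49 and 49. More stayed higher under the other settings, as with the stricter filter (51 and 44) or only the 6 libraries compared (43 and 34).

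Between 28d and 2y no miRNA passed in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 39 miRNAs, where 17.2 are expected by chance, and the lowest adjusted p was 0.139. DESeq2 called 18, of which 8 were higher and 10 lower at 2y, among them miR-181a-3p (log2 fold change -0.97 ± 0.18 SE, adjusted p = 8.95e-06). It also called miR-29a-3p (log2 fold change 1.009) and miR-146b-5p (log2 fold change -1.942), each with a DESeq2 adjusted p = 0.0243. The lowest adjusted p of the 18 (4.51e-06) was that of miR-456-5p, counted as higher. It had 893 counts in 2y replicate 2 and 0 in the other 28d and 2y libraries. In those 5 the counts of this hairpin were on the 3p arm. miR-29a-3p was at 1880.1 ± 151 against 1027 ± 329 CPM (1.83-fold, adjusted p = 0.282) with no overlap between the libraries of both ages, and miR-29b-3p at 318 ± 24.4 against 215 ± 118 CPM. miR-100-5p was at 6894 ± 214 against 17530.0 ± 14625 CPM and miR-146b-5p at 3131 ± 667 against 13246 ± 8838 CPM; miR-100-5p was at 34404 CPM in 28d replicate 1 and at 9685 and 8501 CPM in replicates 2 and 3. miR-499-5p, a muscle miRNA, was at 47.5 ± 36.8 against 234 ± 108 CPM. miR-26-5p was at 325385 ± 78809.6 against 354320.0 ± 182385 CPM, miR-148a-3p at 259192 ± 16233 against 348764 ± 148791 CPM and miR-143-3p at 199511 ± 54935 against 166703 ± 93913 CPM.

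No member of any list passed between 28d and 2y over all tested miRNAs; adjusted over the list alone, 2 hepatocyte-enriched, 2 muscle and 1 leukocyte member were lower. In camera the miR-29 family was higher at 2y (adjusted p = 0.0101, median log2 fold change 0.76 over 4 members). Its adjusted p = 0.564 with an estimated correlation, and 0.138 without 28d replicate 2. The pancreas list also passed in camera, as higher at 2y (adjusted p = 0.0107), although the median log2 fold change of its 4 members was -0.50 in edgeR and 2.65 on the voom scale. With an estimated correlation its adjusted p = 0.564, and without 28d replicate 1 or 2 it was 0.512 or 0.0835. Of 345 miRNAs 53 had no overlap between these ages, 15.4% where chance gives 10.0%. In simulated counts of this comparison, with 375 miRNAs tested, 12.7% of 63 miRNAs changed 2-fold were called, 45.8% of 59 changed 4-fold and 60.3% of 58 changed 8-fold. Those counts had 200 changed miRNAs and the same dispersion at every age. The real mean variance within an age was 1.1172 at 28d and 0.7135 at 2y. The simulated shares therefore do not show how many true changes between 28d and 2y would be called. Without 28d replicate 1 miR-29a-3p, miR-29b-3p and miR-124-3p passed (adjusted p 0.0202, 0.0202 and 0.0240). Their log2 fold changes were then 1.628, 1.555 and 6.605. Without replicate 2 miR-146b-5p passed (log2 fold change -2.517, adjusted p = 0.00437), and without replicate 3 miR-217-5p (log2 fold change 9.144, adjusted p = 0.0241).

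Over the whole span from 1d to 2y, 95 miRNAs changed, 50 higher and 45 lower at 2y. The miR-29 family rose with all of its 4 tested members, the same counts adjusted over the list alone and 3 up and 0 down with the total count alone. These members are both arms of miR-29a and of miR-29b. At 1d the minor arms miR-29a-5p and miR-29b-5p were at 0.277 ± 0.142 and 0.504 ± 0.0702 CPM. The floors of the 1d libraries were 0.398 to 0.424 CPM, so the rises of the minor arms start near the floor. miR-29a-3p was 12.9-fold higher (1880.1 ± 151 against 146 ± 35.3 CPM, log2 fold change 3.69 ± 0.32 SE, adjusted p = 6.18e-05) and miR-29b-3p 14.8-fold (318 ± 24.4 against 21.4 ± 3.56 CPM, adjusted p = 7.26e-05). In camera the adjusted p = 0.00193, and the adjusted p = 0.314 with an estimated correlation. miR-22-3p rose 9.55-fold (256832 ± 88327 against 26886 ± 5117 CPM, adjusted p = 0.000638), miR-26-5p 4.53-fold (325385 ± 78809.6 against 71863 ± 10165 CPM, adjusted p = 0.00265), miR-1388-3p 15.9-fold and miR-1388-5p 13.9-fold. The share of counts at 1d and 2y was 4.60 and 16.7% for miR-22-3p and 12.4 and 21.4% for miR-26-5p. miR-215-5p rose 49.7-fold (adjusted p = 0.00254, and 16.9-fold without 2y replicate 1), with values of 3327, 82.1 and 869 CPM in the 2y libraries against 28.7 ± 9.33 CPM at 1d.

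The mesenchymal list had 7 of 10 members higher and 0 lower at 2y (adjusted over the list alone, 8 up and 0 down, and with the total count alone 1 up and 0 down), miR-145-3p 7.97-fold (adjusted p = 0.000483) and miR-143-3p 5.02-fold (199511 ± 54935 against 39764 ± 4793 CPM, adjusted p = 0.00366) among them. In camera its adjusted p = 0.00197, and the adjusted p = 0.0830 with an estimated correlation. In the leukocyte list 5 of 11 rose and 0 fell, the same counts adjusted over the list alone and 0 up and 0 down with the total count alone (camera adjusted p = 0.0216, and adjusted p = 0.541 with an estimated correlation). miR-146a-5p was 7.51-fold higher (637 ± 155 against 84.8 ± 44.5 CPM), with an adjusted p of 0.00986 that was 0.0503 without 1d replicate 1.

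The miR-17-92 family had 9 of 19 members lower and 0 higher at 2y, the same counts adjusted over the list alone and 0 up and 14 down with the total count alone. miR-18b-5p was 19.5-fold lower (13.7 ± 5.56 against 268 ± 75.7 CPM), miR-106-3p 17.1-fold, miR-363-3p 7.84-fold and miR-20b-5p 7.53-fold, with adjusted p from 7.26e-05 to 0.000133. In camera its adjusted p = 0.000117, and the adjusted p = 0.341 with an estimated correlation. miR-222a-3p fell 9.61-fold (1614 ± 1243 against 15507 ± 7162 CPM, adjusted p = 0.00243, and 16.6-fold without 2y replicate 1) and miR-148a-5p 12.3-fold (adjusted p = 6.18e-05). miR-205a-5p was 11.3-fold lower (27.2 ± 8.35 against 309 ± 46.7 CPM, adjusted p = 0.0350), a call that ended without any 1d or 2y library, 14d replicate 2 or 28d replicate 3 (adjusted p 0.0511 to 0.141). The epithelial list had 3 of 10 members lower and 1 higher (adjusted over the list alone, 1 up and 5 down, and with the total count alone 0 up and 7 down), the muscle list 3 of 7 lower and none higher (adjusted over the list alone, 0 up and 5 down, and with the total count alone 0 up and 6 down). In the group of miR-10, miR-99, miR-100 and miR-125 4 of 9 rose and 1 fell, the same counts adjusted over the list alone and 0 up and 2 down with the total count alone, with miR-10a-5p 4.12-fold higher (17442 ± 2405 against 4237 ± 1472 CPM, adjusted p = 0.000392). In the lipid metabolism list 1 of 10 rose, miR-33-5p (5.05-fold, adjusted p = 0.00293), and none fell, the same counts adjusted over the list alone and 0 up and 4 down with the total count alone. miR-103-3p and miR-107-3p have nearly the same counts in every library and cannot be separated here.

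With scaling to the total count alone 122 miRNAs passed between 1d and 2y, 12 higher and 110 lower, with a median shift of -1.31 in log2. miR-145-3p, miR-146a-5p, miR-10a-5p and miR-33-5p then no longer passed (adjusted p 0.0545, 0.0545, 0.152 and 0.211), and miR-148a-3p, which was 2.50-fold higher with TMM (adjusted p = 0.00864), had a log2 fold change of -0.04. With TMM and without 2y replicate 2 there were 42 higher and 29 lower. The balance turned without 1d replicate 2 (37 higher and 40 lower) and without 28d replicate 1 (51 higher and 56 lower). More were lower also with relative log expression (45 higher and 50 lower), DESeq2 (55 and 70), no filter (28 and 36) or the stricter filter (45 and 48). The same held with only the 6 libraries compared (63 and 68) or without miRNAs at 0 in part of an age's libraries (50 and 53). More stayed higher with upper-quartile factors (50 and 48), limma voom (52 and 50), the replicate block (46 and 35) or the most abundant miRNA left out (49 and 46).

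**Figure D4:**
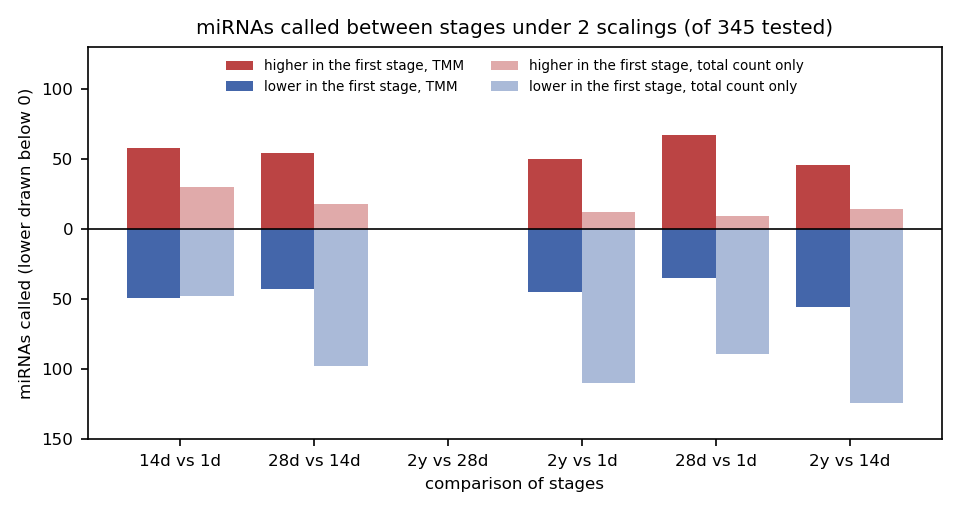
Number of miRNAs called between stages (y axis, higher above and lower below 0) in each of 6 comparisons (x axis), with TMM in full colour and total count only in pale colour. Between 1d and 2y the split was 50 higher and 45 lower with TMM and 12 higher and 110 lower with the total count alone.

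Between 1d and 28d, 102 miRNAs changed, 67 higher and 35 lower at 28d. miR-222a-3p was 31.0-fold lower (501 ± 131 against 15507 ± 7162 CPM, adjusted p = 0.000405), miR-106-3p 19.0-fold lower (adjusted p = 0.000173) and miR-551b-3p 19.9-fold higher (244 ± 89.8 against 12.2 ± 7.97 CPM, adjusted p = 0.000688). miR-215-5p was 15.6-fold higher (9.32-fold without 28d replicate 1), with an adjusted p of 0.0106 that was 0.0507 without 28d replicate 1. miR-33-3p was 16.9-fold higher (116 ± 170.1 against 6.87 ± 0.505 CPM, adjusted p = 0.0285, and 1.68-fold without 28d replicate 1), with 312 CPM in 28d replicate 1 and 8.56 and 27.2 CPM in replicates 2 and 3. Its call ended without any 1 of the 1d libraries, 14d replicate 1 or 28d replicate 1 (adjusted p 0.0670 to 0.514). miR-3156-5p had no count at 28d and was at least 692-fold lower by the floor of 3 counts per library, a call that ended without any 1 of the 6 libraries (adjusted p 0.0725 to 0.108). The miR-17-92 family had 10 of 19 members lower and none higher, the mesenchymal list 8 of 10 higher, the leukocyte list 6 of 11 and the miR-29 family 3 of 4, with no lower member in the last 3 lists. Adjusted over the list alone the counts were 10 lower, and 8, 7 and 4 higher. With the total count alone 12 miR-17-92 members were lower, and 1 mesenchymal, 1 leukocyte and 2 miR-29 members were higher. The minor arms of miR-29a and miR-29b were near the floor at 1d. All 4 lists passed in camera (adjusted p 0.000210, 0.00488, 0.0205 and 0.0161), the leukocyte list with an adjusted p of 0.0521 without 1d replicate 1. With an estimated correlation the adjusted p values were 0.433, 0.102, 0.523 and 0.433. With scaling to the total count alone 98 miRNAs passed, 9 higher and 89 lower, with a median shift of -1.30 in log2, and miR-215-5p and miR-33-3p then no longer passed (adjusted p 0.0689 and 0.0995). With TMM there were 40 higher and 51 lower without 28d replicate 1 and 42 higher and 28 lower without 1d replicate 1. The excess of rises was small with relative log expression (48 higher and 43 lower), upper-quartile factors (49 and 44), no filter (28 and 27) or the stricter filter (53 and 48). The split was 64 and 64 with DESeq2, and 49 and 49 without miRNAs at 0 in part of an age's libraries. With only the 6 libraries compared it was 30 and 41. The excess stayed with limma voom (66 and 43), the replicate block (61 and 31) or the most abundant miRNA left out (67 and 36).

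Between 14d and 2y, 102 miRNAs changed, 46 higher and 56 lower at 2y. miR-143-3p was 10.0-fold higher (199511 ± 54935 against 19882 ± 5483 CPM, adjusted p = 0.000816), miR-145-3p 10.7-fold higher (adjusted p = 0.000500) and miR-215-5p 29.0-fold higher (adjusted p = 0.00646, with 10.2-fold without 2y replicate 1 and 44.8-fold without 2y replicate 2). let-7d-3p was 10.7-fold lower (adjusted p = 0.000323, and 6.91-fold without 14d replicate 1) and miR-205a-5p 39.9-fold lower (16.9-fold without 14d replicate 1), with an adjusted p of 0.00890 that was 0.0509 without 2y replicate 3. miR-9-5p, a neural miRNA, was 13.2-fold lower (35.1 ± 8.08 against 464 ± 119.9 CPM, adjusted p = 0.0223), a call that ended without any 1 of the 6 libraries (adjusted p 0.0522 to 0.0960). Of the lists, the miR-29 family passed in camera with 2 of 4 members higher and none lower (adjusted over the list alone, 3 up and 0 down, and with the total count alone 2 up and 0 down; adjusted p = 0.0344, and adjusted p = 0.630 with an estimated correlation). In the epithelial list 6 of 10 and in the muscle list 4 of 7 members were lower, with none higher (adjusted over the list alone, 0 up and 7 down and 1 up and 5 down, and with the total count alone 0 up and 7 down and 0 up and 6 down). With scaling to the total count alone 138 miRNAs passed, 14 higher and 124 lower, with a median shift of -1.03 in log2. With TMM, leaving out any single 14d or 2y library left between 52 and 64 calls, 34 to 42 higher and 17 to 29 lower, with more higher than lower in each case. More were higher also without 1d replicate 1 (46 higher and 42 lower), 28d replicate 1 (65 higher and 48 lower) or 28d replicate 2 (49 higher and 48 lower). The same held with no filter (31 and 20), the stricter filter (52 and 51) or the replicate block (42 and 33). Without miRNAs at 0 in part of an age's libraries the split was 64 and 53, and with only the 6 libraries compared 69 and 69. More stayed lower with relative log expression (48 and 58), upper-quartile factors (46 and 62), DESeq2 (64 and 71), limma voom (50 and 71) or the most abundant miRNA left out (49 and 52).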

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

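The test of abundant miRNAs at equal depth, the comparison with other ages and the test of leukocyte miRNAs were chosen after the result was seen. Among 694 miRNA names outside the tests, which hold 0.0473% of all counts, 4 reached at least 1000 counts in a library. The conserved name miR-10398-3p had 6916 counts in 28d replicate 3 and 0 in the other 11 libraries. The conserved name miR-7116-3p had 4449 counts in 1d replicate 3 and 0 in the other 11. The predicted miR-96-3p, which carries the number of a known miRNA but another prefix, had 3155 counts in 28d replicate 3 and 60 in the next highest library. The conserved name miR-12094-5p had 1792 counts in 1d replicate 2 and 890 in the next highest.

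28d replicate 1 stood apart from the other 28d libraries, with miR-9-5p 20.9-fold, miR-99-5p 15.5-fold and miR-100-5p 6.57-fold above the higher of them as a share of counts. Deeper sequencing was tested first by thinning: 216 miRNAs kept at least 10 counts in it against 205 and 210, which decides nothing alone, while 45 of 111 abundant miRNAs were over 2-fold above both others at equal depth, which depth does not give. A library of 1d or 14d under this label is argued against by its correlation with the stage means, at most 0.887 for those ages and 0.939 and 0.941 for 28d and 2y. More blood or immune cells in the piece of liver stays open. Of 7 abundant leukocyte-list miRNAs 5 were higher in 28d replicate 1 than in both others, as were 73 of all 111 abundant miRNAs. The median log2 ratio to the mean of the others was 1.44 for that list against 0.84 for all. It was 1.46 for the mesenchymal list, 2.33 for the neural list and -0.86 for the let-7 family. miR-2954-3p, the 1 abundant member of the Z-linked male-biased list, had a ratio of 2.46. A difference between individual birds, that of sex included, was not tested, and the sex of the sequenced birds is not given.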

How the results depend on the processing

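Of 119 calls of named miRNAs, 81 stayed past the threshold with each library left out in turn. Under every other setting but the fold threshold, 68 stayed, the fit of only the 6 libraries compared included. The fold threshold was not applied to single calls. Leaving out miRNAs with 0 counts in part of an age's libraries was chosen after the data were seen. Of 4891 log2 fold changes over all settings, 16 changed direction with a call in the main or the alternative fit. Changes of direction without a call in either fit were not counted. All 16 came with scaling to the total count alone, which moves the median of all miRNAs. They were 3 of 52 values between 14d and 28d and 13 of 53 between 1d and 2y. Between 14d and 28d these were miR-27b-3p -0.05, miR-126-3p -0.31 and miR-10a-5p -0.04. Between 1d and 2y they were miR-148a-3p -0.04, miR-148a-1-5p -1.0, miR-30a-3p -0.95, miR-107-3p -0.87, miR-103-3p -0.87, miR-146c-3p -0.22, miR-146c-5p -0.11, miR-126-3p -0.86, miR-199-5p -0.11, miR-200a-3p -0.15, miR-429-3p -1.12, miR-125-5p -0.02 and miR-30e-5p -1.29. Without a filter on low counts 48 miRNAs passed between 1d and 14d, 56 between 14d and 28d, 55 between 1d and 28d, 51 between 14d and 2y and 96 across ages; the cause was not tested. DESeq2 called 18 between 28d and 2y; the cause was not tested. With each library left out the counts ranged from 50 to 118 (1d and 14d), 61 to 91 (14d and 28d), 0 to 3 (28d and 2y) and 52 to 113 (14d and 2y), where fewer libraries are tested. With an estimated correlation 0 lists passed between 1d and 14d, 0 between 28d and 2y, 0 between 1d and 2y, 0 between 1d and 28d and 0 between 14d and 2y. fry, which asks another question, called 8, 7, 0, 8 and 7 lists for 14d against 1d, 28d against 14d, 2y against 28d, 2y against 1d and 2y against 14d. With each library left out, 0 to 3 lists passed between 28d and 2y. With the replicate number as a block (replicate block) 70 miRNAs passed between 1d and 14d, and 1 list between 28d and 2y, where pancreas ended (pancreas, 2y vs 28d, adjusted p 0.130). The numbers do not pair the birds: same-numbered libraries had correlations of -0.103 to 0.375 over 18 pairs, and 4 of 12 libraries correlated best with their own number. Depth limits miRNAs near 1.90 CPM, the highest floor, that of 28d replicate 3.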

Other observations

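The tests of arm names and of the counting floor, and of a single 28d library, were chosen after the result was seen. The balance between the arms of a miRNA hairpin differed with age. Of 69 hairpins with counts on both arms, 39 differed in the log2 ratio of the 5p to the 3p arm (exact permutation of the F statistic, adjusted over the hairpins), with a median largest difference between ages of 2.43 in log2. For miR-148a, whose main arm is 3p, the ratio was -7.27 ± 0.32, -6.96 ± 0.46, -11.35 ± 0.95 and -12.27 ± 0.48 at 1d, 14d, 28d and 2y (mean ± SD of 3 pigeons, adjusted p = 0.00551 by exact permutation). For miR-26, with a main 5p arm, it was 8.25 ± 0.36, 9.83 ± 0.08, 12.12 ± 0.83 and 12.94 ± 0.21. miR-30d had its highest mean at 14d (10.00 ± 0.15) and its lowest at 1d (4.81 ± 0.61), and miR-145 was at 5.33 ± 0.15 at 14d and 0.78 ± 0.13 at 28d. The minor arm relative to the main arm was lowest at 28d or 2y in 26 of the 39 hairpins. This is a ratio, which a rise of the main arm also lowers, and not the level of the minor arm. The higher arm changed between ages in 2, miR-33 and miR-7a.

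Arm names assigned library by library are argued against as the source of these ratios, since arms were exchanged between libraries in 1 of all 69 hairpins, miR-456, which was not called, and 37 of the 39 that differed had the same higher arm in all 12 libraries. The minor arm near the counting floor is argued against by the hairpins with at least 10 counts on both arms in every library, of which 29 of 50 differed. A library-wide shift of the minor arm relative to the main arm was present. The median over hairpins of the deviation of this log2 ratio was 0.4527 to 0.5886 at 1d and 0.1824 to 0.2278 at 14d. It was -0.3918 to -0.1485 at 28d and -0.5254 to -0.2761 at 2y. An equal shift in all hairpins does not account for all of the differences, since 33 of the 39 still differed with each library's median deviation subtracted. A loss that differs in size between hairpins was not tested. A candidate explanation is a change with age in which arm is kept or in its modification, which was not tested. Age and any unrecorded difference in handling between the groups stay open.

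Between 28d and 2y no miRNA passed in edgeR, against 95 to 107 in the other comparisons of ages, with 39 at an unadjusted p under 0.05 and 18 calls by DESeq2. One 28d library widening the spread stays open. Without 28d replicate 1, 3 miRNAs passed and 51 of 401 had an unadjusted p under 0.05 in edgeR. That fit has fewer libraries and cannot decide the question. The mean variance within an age was 1.1172 at 28d and 0.7135 to 0.8580 at the other ages. A smaller difference between 28d and 2y may account for the lack of calls. The between-stage part of the mean squared difference in log2(CPM + 1) was 0.1953, and 1.93 to 2.18 in the other comparisons. With single 28d or 2y libraries left out it ranged from -0.0035 without 28d replicate 2 to 0.4413 without 28d replicate 3.

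The real split of the 12 libraries into 4 groups of 3 was set beside other splits drawn at random, 100 in all. Only 1 of 100, the real one, gave as many as 156 miRNAs, with 32 as the highest of the others. A split by chance is thus unlikely, though a share of 1 in 100 is the lowest possible here. Differences in handling that follow age are not tested by it. For pairs of ages the 10 splits of 6 libraries are too few for a share under 0.05. Between 1d and 14d the real split called 107 miRNAs and the highest other split 0, and 1 and 1 lists, with 1 and 6 of 10 splits at the real counts or above. Between 14d and 28d the real split called 97 miRNAs and the highest other split 0, and 0 and 1 lists, with 1 and 10 of 10 splits at the real counts or above. Between 28d and 2y the real split called 0 miRNAs and the highest other split 0, and 2 and 2 lists, with 10 and 3 of 10 splits at the real counts or above. Between 1d and 2y the real split called 95 miRNAs and the highest other split 0, and 4 and 4 lists, with 1 and 2 of 10 splits at the real counts or above. Between 1d and 28d the real split called 102 miRNAs and the highest other split 0, and 4 and 2 lists, with 1 and 1 of 10 splits at the real counts or above. Between 14d and 2y the real split called 102 miRNAs and the highest other split 0, and 1 and 1 lists, with 1 and 4 of 10 splits at the real counts or above.

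Some miRNAs had 0 counts in 1 or 2 libraries of an age and at least 100 in another library of that age. miR-456 had its counts on the 3p arm in 8 libraries and on the 5p arm in 4, as in 1d replicate 1 (0 and 3309 counts on the 5p and 3p arm) and 1d replicate 2 (3845 and 0). miR-19a-3p had 0 counts in 2 of the 1d libraries and 7651 in the third. In all 56 such cases, 27 with 1 library at 0 and 29 with 2, occurred in 43 miRNAs, 23 of them tested. miR-217-5p of the pancreas list was at 85.3 CPM in 28d replicate 3 and at 0 in the other 28d libraries.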
